A study of Mus musculus with 4 samples.

How the data were processed

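The arrays were 1-colour Agilent arrays of mouse transcripts, labelled with Cy3 per the labels by low-input amplification from total RNA. Per the file headers they were read with Feature Extraction 10.10.1.1 under the protocol GE1_1010_Sep10, and the probe coordinates are on mm9. The deposited text files give the brightness of each spot on a linear scale of intensity, after background subtraction and detrending within the array, and this processed signal was the starting point. Per the file headers the same files hold the raw mean brightness and the local background as intensity, and flags of 0 or 1 for saturation, distance from background and uneven spots. The authors also deposited a matrix of log2 values. Those values were the log2 processed signal plus 1 constant per array, within 0.01 for 100% of the probes, and their median was 4.4367 on each of the 4 arrays, so that they amount to median scaling. The constants were -0.0766 and -0.1977 for the wild-type arrays and 0.144 and 0.0766 for the deletion-mutant arrays. How the authors tested their values is not given in the sources used here.

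Spots with a flag for uneven signal or as a population outlier were left out (116, 142, 127 and 122 spots), control spots were left out, and the remaining spots of a probe were averaged in log2. Of 55681 non-control probes, 11 had every spot marked on an array and were left out. Median signals were 23.01 and 24.99 intensity units on the wild-type and 19.73 and 20.7 on the deletion-mutant arrays. From each array its 75th percentile over non-control probes was subtracted in log2. A probe counted as well above background when at least a share of 0.5 of its spots was marked so, and 25162 probes that were well above background on both arrays of at least 1 group were kept. A feature was a gene name of the array's design, represented by its brightest kept probe, or an unnamed probe by itself, which gave 18093 features, 11734 of them with a gene-like name. Gene names were compared with a RefSeq gene list of a later assembly by accession, and 12045 features matched, of which 866 now have another symbol. Exon, intron or untranslated position of a probe was not analysed here, since no annotation of mm9 was used. Of 4969 genes with several kept probes, 136 had probes past the threshold in both directions and 0 had probes at least 2-fold changed in both directions by limma (11604 features had an unadjusted p under 0.05).

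Groups were compared with limma 3.58.1 (lmFit and eBayes without trend or robust estimation) in R 4.3.3 with data.table (version 1.17.8). The residual degrees of freedom were 2, the prior degrees of freedom 2.18, the prior SD 0.0747 and the median standard error of a log2 fold change 0.0735. P-values were adjusted by Benjamini and Hochberg over all features, with a threshold of 0.05, and a change of at least 2-fold was counted besides. Fixed lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, each adjusted over 25 lists. The lists are those of ERK feedback and output, immediate-early genes, the EGFR family, other receptor tyrosine kinases, DNA replication, mitosis, p53 targets, collagens and matrix, matrix proteases, smooth muscle and SRF targets, TGF-beta and YAP targets, interferon response, chemokines and NF-kB targets, glycolysis and hypoxia, cholesterol and fatty acid synthesis, ATF4, ER chaperones, heat shock and NRF2, methylation enzymes, ribosome biogenesis, Wnt and Notch, adhesion, and markers of adipocytes, bone and cartilage, epithelium, skeletal muscle, endothelium and leukocytes. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

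The grouping, the test, the lists, the rule for naming genes and most alternatives were chosen before the data were examined. Genes named were the Egfr probes, the 12 largest rises and 12 largest falls among named genes that passed, were well above background and unsaturated on all 4 arrays and had both arrays of a group above both of the other. To these were added the 5 genes per direction with the largest bound, for genes at background in 1 group, and up to 4 members of each list with the largest change, or a pair per direction where at least 3 members went each way. These alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the authors' log2 values, no background filter, a filter on all 4 arrays, an intensity trend with robust variances, the mean of a gene's probes, every probe by itself, the replicate number as a block, and leaving out each array. Scaling on the 4 brightest E1A spike-in probes and on the 75th percentile of probes detected on all 4 arrays were chosen after the data were seen. Families of genes by name stem were also formed after the values were seen.

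The procedure was tested on simulated data of 18093 features with the spread of these arrays, in which 200 features and 1 list were changed. It recovered 22% of changes of 0.5 (log2), 66% of changes of 1, 90% of changes of 2 and 92% of changes of 3, each out of 50. There were 11 false calls, 6.6% of all calls. The changed list had an adjusted p of 8.31e-52 and none of the other lists passed. Few features were changed in the simulation, whereas 58.8% passed in the data, so the adjusted threshold differs and these rates do not carry over. Spread was drawn independently for each feature, so the list result does not cover correlated genes. The number of arrays, 2 per group, limits the precision of every value given.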

Results

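The arrays measured messenger RNA levels in NIH3T3 cells, an immortalised line of mouse embryonic fibroblasts, that expressed either wild-type EGFR or a deletion mutant of EGFR. EGFR is the receptor for epidermal growth factor, a receptor tyrosine kinase that signals through the RAS and ERK cascade among other routes. The labels give neither the extent of the deletion nor the species of the receptor. Each sample was hybridised as Cy3-labelled cRNA to a 1-colour Agilent array, on which the brightness of a spot reports the amount of the transcript that its probe matches. There were 2 groups of 2 arrays, and per the labels the cells were at steady state. The labels mention separate cDNA preparations but not separate cultures, so the arrays of a group may share an RNA extract. The p-values therefore measure only the spread between these arrays, which may be technical. All 4 arrays lay on 1 slide with the groups in different columns, so a column effect and a group effect cannot be told apart.

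In the wild-type arrays, 26104 probes (46.9%) and 25236 probes (45.3%) were well above background. The corresponding numbers in the deletion-mutant arrays were 24401 (43.8%) and 23863 (42.9%). No spot was saturated, and the 75th percentile of the signal lay between 327 and 366.6 intensity units on the 4 arrays. Across the 18093 tested features, which are genes or unnamed transcripts and not independent replicates, the correlation was 0.9976 between the wild-type arrays and 0.9968 between the deletion-mutant arrays. Between arrays of different groups it lay between 0.9605 and 0.9611. The difference between the group means had an SD of 0.835 (log2) across features, against 0.201 for the difference between the wild-type arrays and 0.243 for that between the deletion-mutant arrays.

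The comparison asked which transcripts differ between cells with the deletion mutant and cells with the wild-type receptor. Of 24 measured genes in the list of ERK feedback and output, 22 were higher in deletion-mutant cells, among them Dusp4, a phosphatase that inactivates ERK, which was 8.49-fold higher (log2 fold change 3.08 ± 0.068 SE, n = 2 arrays per group, limma adjusted p = 0.000172). All 28 measured genes of DNA replication and all 30 of mitosis were higher in them as well, such as Cdc6, a licensing factor for replication origins, at 3.41-fold (1.77 ± 0.067). Fibroblast matrix genes went the other way: 24 of 34 measured collagens and matrix proteins were lower, including Postn (periostin), which was 28.8-fold lower (-4.85 ± 0.056, adjusted p = 0.000146). Acta2, the smooth muscle actin of activated fibroblasts, was 16-fold lower (adjusted p = 0.000146). The ERK, replication, mitosis and matrix lists passed as lists with a preset correlation between genes and not with an estimated correlation (adjusted p = 0.239, 0.239, 0.286 and 0.274). The test with an estimated correlation rests on 2 residual degrees of freedom, so it has little power. Its failure does not show that correlation between genes accounts for these shifts.

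Altogether 10631 of the 18093 features (58.8%) passed an adjusted p of 0.05, of which 6260 were higher and 4371 lower in deletion-mutant cells. A change of at least 2-fold was found for 2423 features (13.4%), 1074 of them higher and 1349 lower. With normexp background correction, whose offset compresses the folds of dim probes, it was found for 1285 features, 693 of them higher and 592 lower. By the fitted fold, 57 features were at least 10-fold higher and 100 at least 10-fold lower. The fitted fold is not a measured one where a group lay at background: 693 features were well above background on both arrays of the wild-type group only and 169 on both arrays of the deletion-mutant group only. Among the 16572 features that were well above background on all 4 arrays, 903 were at least 2-fold higher and 810 at least 2-fold lower.

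**Figure D1:**
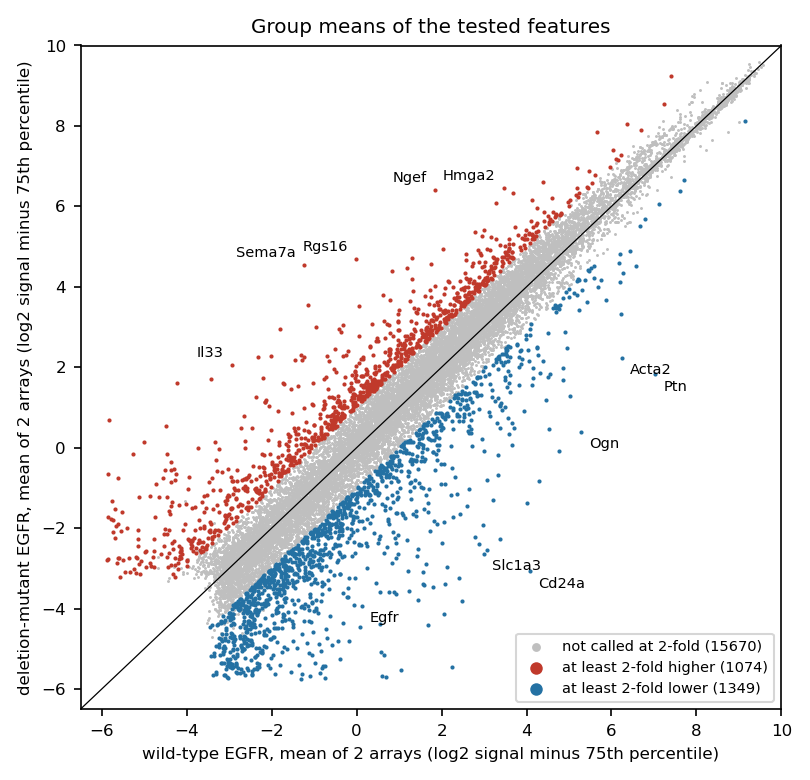
Mean of the 2 deletion-mutant arrays (vertical axis) against the mean of the 2 wild-type arrays (horizontal axis) for each of 18093 features, in log2 signal minus the array's 75th percentile, with the line of equality. Red points are the 1074 features at least 2-fold higher and blue points the 1349 at least 2-fold lower past the adjusted threshold; features below about -3.5 lie at background.

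The split into higher and lower features depended on the scaling of the arrays. Of the changed features, 58.9% were higher under the 75th percentile, 73.5% under median scaling, 65.8% under scaling on E1A spike-ins, 51.1% under quantile normalization and 38.9% under the 75th percentile of the detected probes. Of those changed at least 2-fold, the higher share was 44.3% under the 75th percentile and 61.3%, 52.7%, 42.9% and 26.9% under the same alternatives in that order. Only 42.9% to 46.9% of probes were well above background on an array, so median scaling rests on a signal at background. The median of all features shifted by 0.18 (log2) under median scaling, by 0.081 under spike-in scaling, by -0.062 under quantile normalization and by -0.19 under the percentile of the detected probes. None of these alternatives called a feature in the direction opposite to the one given here. That says little, since they moved the median of all features by only -0.19 to 0.18 (log2). Scaling on the median, the spike-ins or a percentile moves every log2 fold change by the same amount. Shifts this small leave little room for a call to turn direction.

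The largest rise among genes measured above background on every array was that of Sema7a, a membrane-anchored semaphorin that binds integrins (probe on chromosome 9, 57810607 to 57810666, mm9). It was 54.7-fold higher, with a mean of -1.24 ± 0.045 (SD, n = 2) in wild-type and 4.54 ± 0.054 in deletion-mutant arrays (limma adjusted p = 0.000146). Il33, a cytokine of the interleukin-1 family, was 31.6-fold higher (log2 fold change 4.98 ± 0.157 SE), and Rgs16, which shortens signalling by G proteins, was 25.9-fold higher (4.69 ± 0.064). Enzymes among the largest rises were Upp1, the uridine phosphorylase, at 25.7-fold and Gch1, the first enzyme of tetrahydrobiopterin synthesis, at 23.8-fold. Ngef, an exchange factor that acts downstream of Eph receptors, was 23.5-fold higher, and Evi2a was 27.1-fold higher. Smaller rises were seen for Tmem179 (15.5-fold), the urea transporter Slc14a1 (15.3-fold), Plxdc1 (12.4-fold), the cardiac troponin Tnnt2 (12.4-fold) and the integrin chain Itgb7 (12.2-fold). All 12 had adjusted p-values between 0.000146 and 0.000404.

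Among genes measured above background on every array, the largest fall was that of Cd24a, a sialoglycoprotein of the cell surface (probe on chromosome 10, 43303706 to 43303765, mm9). It was 141-fold lower, with 4.07 ± 0.026 (SD, n = 2) in wild-type and -3.06 ± 0.060 in deletion-mutant arrays (limma adjusted p = 0.000146). The other large falls included Svep1 (50.2-fold lower), the pentraxin Ptx3 (48.5-fold), the heparin-binding growth factor Ptn (36.6-fold), the complement protease C1s, now called C1s1 (35-fold), thrombospondin 1, Thbs1 (32.2-fold), the proteoglycan Ogn (29.3-fold) and periostin. The rest were the glutamate transporter Slc1a3 (49.3-fold lower), the myosin light chain Myl9 (38.5-fold), Asb4 (34.5-fold) and the collagen-binding integrin chain Itga11 (29.5-fold). The adjusted p was 0.000146 for each of these 12 genes.

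**Figure D2:**
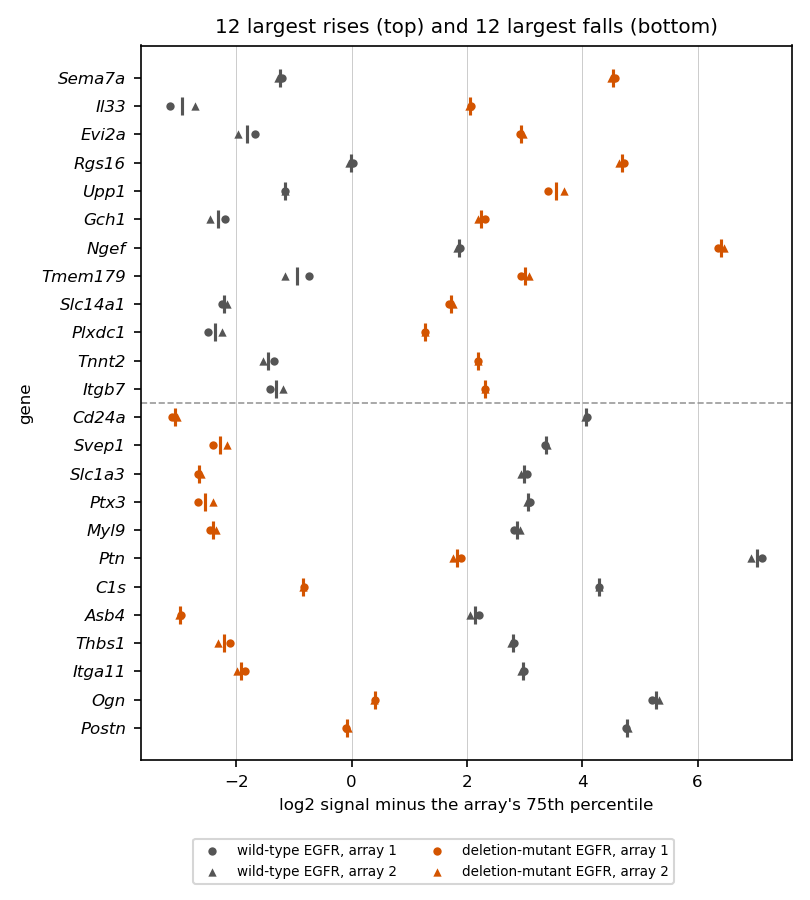
Log2 signal minus the array's 75th percentile (horizontal axis) on each of the 4 arrays for the 12 genes with the largest rise and the 12 with the largest fall (vertical axis); grey is wild-type EGFR, orange deletion-mutant EGFR, circles and triangles are the arrays of a group and the vertical ticks its mean. For every gene the arrays of a group lie close together, as for Cd24a at 4.09 and 4.06 against -3.11 and -3.02.

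Some genes were detected in 1 group and lay at background in the other, so that only a lower bound of the fold could be given. The bound compares the mean of the bright group with the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The ubiquitin ligase Rnf183 was at least 37-fold higher in deletion-mutant cells (adjusted p = 2e-04). Lgr6, a receptor for R-spondins, was at least 19.5-fold higher, Mctp2 at least 13.3-fold, the muscle acetylcholine receptor subunit Chrna1 at least 10.9-fold and the lectin Siglec15 at least 10.8-fold. In the other direction, Gdpd2 was at least 58.9-fold lower (adjusted p = 0.000248), the aldehyde dehydrogenase Aldh1a7 at least 50.3-fold, the collagen Col12a1 at least 41.2-fold, the small proteoglycan Aspn at least 36.7-fold and the cytochrome P450 Cyp1b1 at least 33.9-fold.

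Mouse Egfr transcript was detected in wild-type cells and not in deletion-mutant cells. The brightest of the 3 Egfr probes, at chromosome 11, 16813815 to 16813874 (mm9), had 0.12 ± 0.025 (SD, n = 2) in wild-type arrays, and its -3.93 ± 0.081 in deletion-mutant arrays was not well above background. Egfr was at least 11.5-fold lower there (limma adjusted p = 0.000146). A probe at 16783556 to 16783615 was at least 2.22-fold lower, and a probe at 16787172 to 16787231 was not well above background on any of the 4 arrays. Since the labels do not give the species of the receptor that was introduced, a mouse probe may not match it, and these values do not check the labels. The probe for Wdr92, which lies within 2 Mb of Egfr and was chosen after its values were seen, was 4.53-fold higher (adjusted p = 0.000294).

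**Figure D3:**
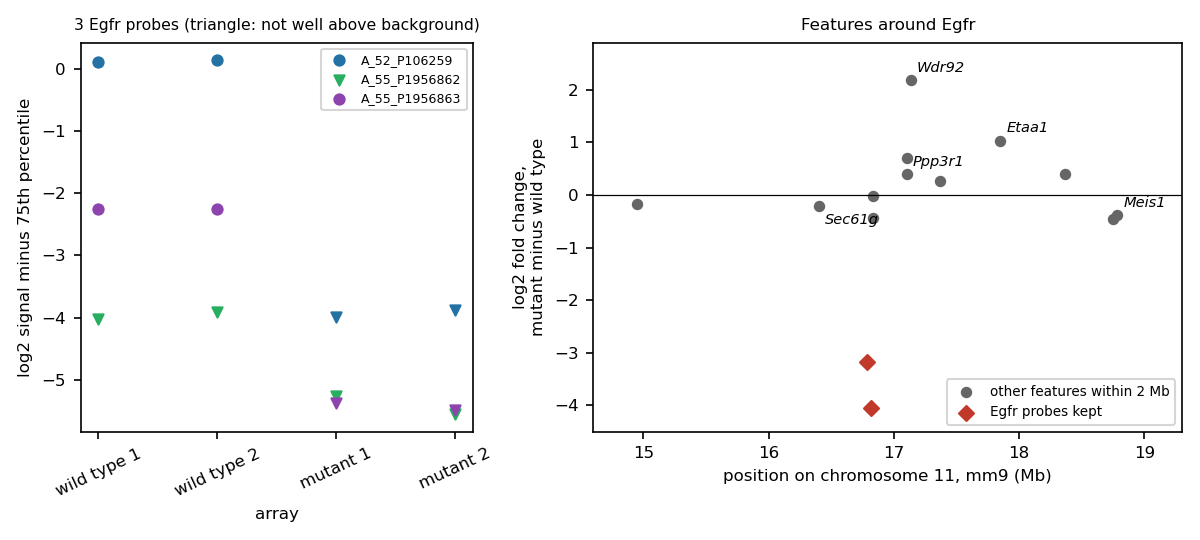
Left, log2 signal minus the 75th percentile (vertical axis) of the 3 Egfr probes on each of the 4 arrays (horizontal axis), where triangles are values not well above background. Right, log2 fold change of deletion mutant minus wild type (vertical axis) against the mm9 position in Mb on chromosome 11 (horizontal axis) for the Egfr probes that passed the background filter, at -4.04 and -3.17, and the 12 other features within 2 Mb.

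Of 28 gene lists fixed before the data were examined, 25 had at least 5 measured members and were tested with camera, which asks whether a list shifted relative to all other features. With the preset correlation of 0.01, 10 lists passed, 7 of them upward and 3 downward. With an estimated correlation no list passed, and with fry, which asks only whether a list moved in 1 direction, 23 of 25 did. The former test rests on 2 residual degrees of freedom and has little power. The replication list failed it with an estimated correlation of -0.035, below the preset 0.01, so correlation does not account for that failure. Estimates were also below the preset for ribosome biogenesis (0.0032), heat shock (-0.0023) and interferon (-0.017). They were above it for mitosis (0.1), ATF4 (0.068), matrix (0.046), smooth muscle (0.041), ERK (0.019) and cholesterol (0.019). For these lists the p-values with the preset correlation may be too small. Member counts adjusted over the list alone were the same as those adjusted over all features, except for the 4 lists where another count is given. Members outside the naming rule are named after their values were seen, wherever a count was 5 or fewer. A fit without 1 array leaves 1 array in that array's group, so its spread comes from the other group alone.

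**Figure D4:**
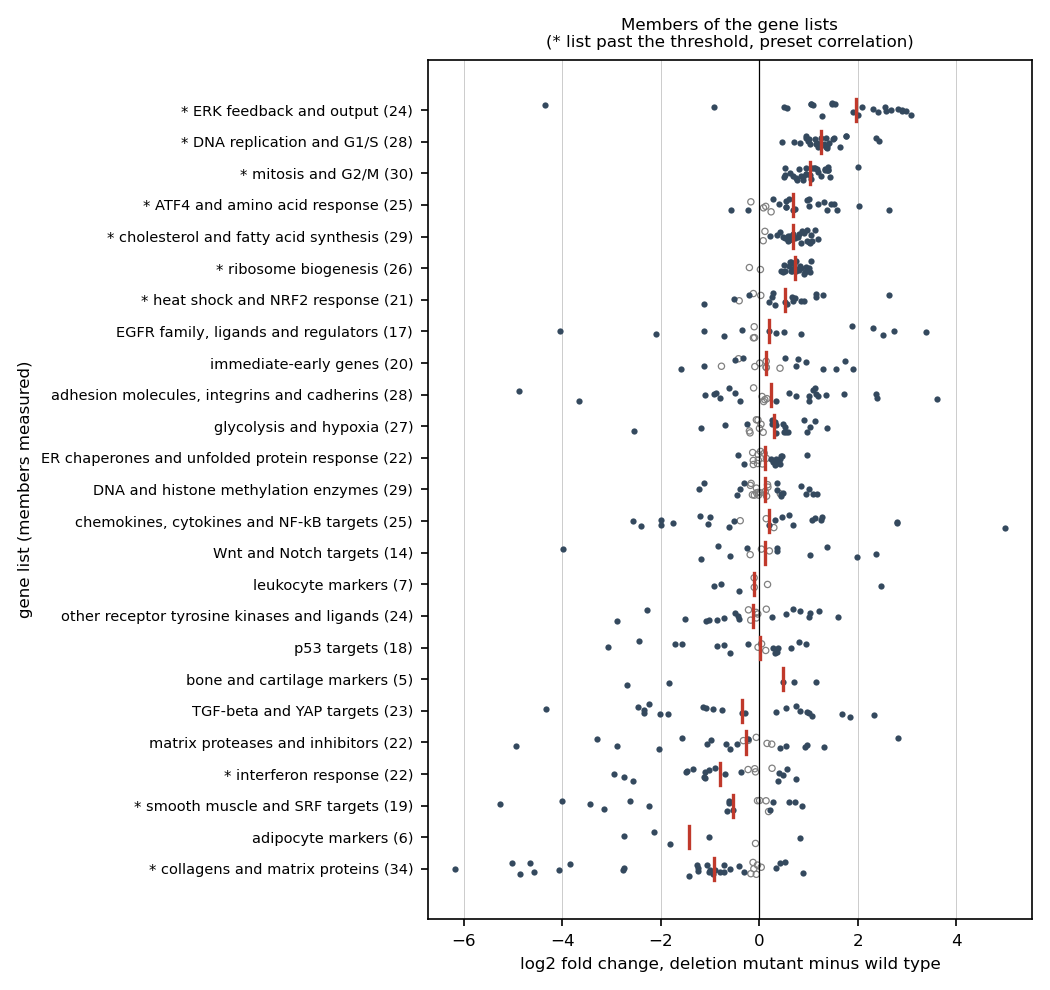
Log2 fold change of deletion mutant minus wild type (horizontal axis) for each measured member of the 25 tested lists (vertical axis, ordered by mean); filled points passed the adjusted threshold, open points did not, red bars are list medians and asterisks mark the 10 lists past the threshold with the preset correlation. Medians range from 1.96 for the ERK list to -1.42 for adipocyte markers, a list that did not pass.

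Feedback and output genes of the ERK cascade rose in 22 of 24 cases, 20 of them by at least 2-fold (adjusted p = 1.49e-07 for the list, and adjusted p = 0.239 with an estimated correlation). Hmga2, a chromatin protein of fetal and tumour cells, rose 7.89-fold (log2 fold change 2.98 ± 0.056 SE), and the ETS transcription factor Etv4 rose 7.51-fold (2.91 ± 0.060). The 2 members that fell were the ephrin receptor Epha4, at least 4.35-fold lower, and Spry1, an inhibitor of receptor tyrosine kinase signalling, which fell by 0.92 ± 0.131 (log2). Under all 5 other scalings, of which the authors' values repeat median scaling, the same 22 were higher and the same 2 lower. This is weak support, since these scalings moved the median of all features by only -0.19 to 0.18 (log2). Immediate-early genes, which growth factors induce within minutes, were mixed: 8 rose, 4 fell and 8 did not pass, and the list did not shift (adjusted p = 0.409). Their split was 12 higher and 3 lower under median scaling and 7 and 5 under the percentile of the detected probes. The transcription factors Klf4 (3.77-fold) and Jun (3.34-fold) rose, while Klf2 (3.02-fold), the antiproliferative Btg2 (2.16-fold), Dusp1 (-0.49, log2) and Jund (-0.33) fell.

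In the list of the EGFR family with its ligands and regulators, 9 of 17 members rose and 5 fell (adjusted p = 0.745), which turned to 7 and 8 under the percentile of the detected probes. Ereg (epiregulin), a ligand of EGFR, rose 10.4-fold (3.38 ± 0.075 SE, log2), and Btc (betacellulin), another ligand, was at least 3.83-fold higher. Besides Egfr, the members that fell were the ligand Nrg1 (4.28-fold), Egf (-1.12), Lrig3 (-0.72) and Rhbdf2 (-0.34), while Adam10 (-0.12), Erbb2 (-0.10) and Adam17 (-0.093) did not pass. Other receptor tyrosine kinases and their ligands did not shift as a list (adjusted p = 0.254), with 8 of 24 higher and 10 lower, but passed downward with every probe as a feature (adjusted p = 0.0417). The angiogenic factor Vegfa rose 3.02-fold, whereas Gas6, the ligand of Axl, fell 7.39-fold and Figf (now Vegfd) 4.85-fold.

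All 28 measured genes of DNA replication and the G1/S transition rose, 22 of them by at least 2-fold (adjusted p = 6.15e-10, and adjusted p = 0.239 with an estimated correlation). The largest rises were those of the transcription factors E2f8 (5.39-fold, 2.43 ± 0.055 SE) and E2f2 (5.14-fold, 2.36 ± 0.082), followed by Cdc6 and by Cdc45, a part of the replicative helicase (3.38-fold). All 30 genes of mitosis and G2/M rose, 16 by at least 2-fold (adjusted p = 2.41e-09, and adjusted p = 0.286 with an estimated correlation). The spindle checkpoint kinases Ttk (2.70-fold) and Bub1 (2.64-fold) and the topoisomerase Top2a (2.64-fold) rose, and the mitotic kinase Aurkb was at least 1.67-fold higher. With such members at their bound, the median of the mitosis list was 0.99 (log2) in place of 1.04. Both lists had every member higher under all 5 other scalings, whose small shifts make this weak support. Targets of p53 did not shift (adjusted p = 0.39): 7 of 18 rose and 8 fell, or 9 and 7 under median scaling, 3 and 9 under quantile normalization and 4 and 9 under the percentile of the detected probes. Their median was 0.013 where their mean was -0.41 and the test pointed down. Gtse1, which is expressed in G2, rose 1.92-fold and the cytokine Gdf15 at least 1.5-fold, the death receptor Fas fell 8.38-fold, and Perp, a desmosomal protein, was at least 1.92-fold lower. The members that did not pass were Sesn2 (0.13), Bax (0.049) and Ccng1 (-0.023).

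Of 34 collagens and matrix proteins, 24 fell, 15 by at least 2-fold, and 4 rose (adjusted p = 1.4e-07, and adjusted p = 0.274 with an estimated correlation). Col12a1, Thbs1 and Postn led the falls. The 4 that rose were the proteoglycan Lum (1.84-fold), Col6a3 (1.43-fold) and the basement membrane collagens Col4a1 (0.42, log2) and Col4a2 (0.34). Between 23 and 27 members were lower under the other scalings. Matrix proteases and their inhibitors fell in 11 of 22 cases and rose in 6, or 12 and 7 adjusted over the list alone, and the list did not pass (adjusted p = 0.104). It passed downward under median scaling (adjusted p = 0.0272) and with every probe as a feature (0.0417). The urokinase receptor Plaur rose 7.02-fold and cathepsin L, Ctsl, 2.48-fold, while the protease inhibitor Serpine2 fell 9.80-fold and the brightest probe of the aggrecanase Adamts5 was at least 29.8-fold lower. Not past the threshold were Lcn2 (-0.32), Plat (0.26), Adamts4 (-0.22), Mmp9 (0.16) and Plau (-0.059).

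Contractile and actin genes of the smooth muscle and serum response factor list fell in 10 of 19 cases and rose in 5, or 6 adjusted over the list alone (adjusted p = 0.0306, and adjusted p = 0.39 with an estimated correlation). This call was lost without wild-type replicate 2 (adjusted p = 0.058), under the percentile of the detected probes (0.0532) and among features above background on all 4 arrays (0.172). Myl9 and Acta2 fell most among its fully measured members. The members that rose were Tagln2 (1.83-fold), the tropomyosin Tpm4 (1.65-fold), Actn1 (0.60, log2), Smtn (0.27) and Myh9 (0.23), and Flna (0.19), Zyx (0.14), Tpm2 (-0.034) and Vcl (0.008) did not pass. Targets of TGF-beta and YAP were divided, with 10 of 23 higher and 13 lower (adjusted p = 0.234). The activin subunit Inhba rose 5.06-fold and Tgfb1 itself 3.58-fold. The inhibitory SMAD protein Smad6 was at least 7.12-fold lower, and Id3, a target of BMP signalling, fell 5.50-fold. As a list they passed downward under median scaling (adjusted p = 0.0319).

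Genes of the interferon response fell in 13 of 22 cases and rose in 5 (adjusted p = 0.00842, and adjusted p = 0.289 with an estimated correlation). The call was lost under the percentile of the detected probes (adjusted p = 0.0551). Ifi44 was at least 3.15-fold lower and the guanylate-binding protein Gbp3 at least 2.87-fold lower. Gbp3 lost its call without wild-type replicate 1 or 2, where its fitted log2 change was -3.01 and -2.88. The members that rose were the class I antigens H2-D1 (1.68-fold), H2-K1 (0.48, log2) and B2m (0.38), Ifit2 (0.41) and the chemokine Ccl5 (1.47-fold). Ccl5 lost its call without wild-type replicate 1 or 2, where its log2 change was 0.583 and 0.537. Isg20 (0.26), Stat2 (-0.23), Irf1 (-0.090) and Ifit1 (-0.075) did not pass. Chemokines, cytokines and NF-kB targets were evenly divided, with 12 of 25 higher and 10 lower (adjusted p = 0.914), or 10 and 11 under the percentile of the detected probes. Their median was 0.19 and their mean 0.10, where camera pointed down and fry up. Besides Il33, the cytokine Il11 rose 6.95-fold, while complement C3 fell 5.92-fold and Il6 was at least 1.29-fold lower. Nfkbiz (-0.39), Birc3 (0.30) and Tnfaip3 (0.14) did not pass.

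Cholesterol and fatty acid synthesis genes rose in 27 of 29 cases and none fell (adjusted p = 2.73e-07, and adjusted p = 0.239 with an estimated correlation). Among them were the sterol enzymes Lss (2.28-fold, 1.19 ± 0.061 SE), Mvd (2.20-fold) and Idi1 (2.08-fold). The other members, Me1 (0.12) and Srebf1 (0.082), did not pass. Between 24 and 28 members were higher under the other scalings. Ribosome biogenesis genes rose in 24 of 26 cases (adjusted p = 1.94e-06, and adjusted p = 0.239 with an estimated correlation), and Pes1 (-0.20) and Npm1 (0.025) did not pass. The RNA helicase Ddx21 rose 2.09-fold (1.06 ± 0.075), the ribosome assembly factor Rrs1 2.05-fold, the pseudouridine synthase Dkc1 2.01-fold and Nop16 1.97-fold. Between 23 and 25 members were higher under the other scalings, and 1 member was lower under quantile normalization and under the percentile of the detected probes.

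Genes driven by ATF4, which responds to amino acid shortage, rose in 19 of 25 cases, or 20 adjusted over the list alone, and fell in 2 (adjusted p = 0.00018, and adjusted p = 0.326 with an estimated correlation). Slc7a11, the cystine transporter, rose 6.18-fold with only 1 wild-type array above background, Cth, an enzyme of cysteine synthesis, 4.08-fold, the secreted Stc2 2.99-fold and Chac1, which degrades glutathione, 2.86-fold. Slc7a3 (-0.56) and Pycr1 (-0.24) fell, and Slc6a9 (0.24), Ddit3 (-0.17), Sesn2 (0.13) and Slc3a2 (0.087) did not pass. Heat shock and NRF2 genes rose in 15 of 21 cases and fell in 3 (adjusted p = 0.0385, and adjusted p = 0.326 with an estimated correlation). That call was lost without deletion-mutant replicate 2 (adjusted p = 0.0702), under median scaling (0.0633), quantile normalization (0.0718) and spike-in scaling (0.053), and among features above background on all 4 arrays (0.103). Besides Slc7a11, Srxn1, which repairs oxidised peroxiredoxins, rose 2.46-fold, whereas the heme oxygenase Hmox1 (2.17-fold), the glutathione transferase Gsta4 (1.42-fold) and Osgin1 (-0.21) fell. Hspa1a (-0.41), Bag3 (-0.12) and Hspb8 (0.033) did not pass.

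Chaperones of the endoplasmic reticulum and genes of the unfolded protein response did not shift (adjusted p = 0.409), with 10 of 22 higher and 2 lower, Sel1l (-0.42) and Vimp (-0.32). This split turned to 5 higher and 6 lower under quantile normalization and to 4 and 6 under the percentile of the detected probes. Manf, a secreted protein of that compartment, rose 1.37-fold, and the chaperone Hyou1 rose 1.95-fold, a call that was lost with no background filter (adjusted p = 0.0525). Glycolysis and hypoxia genes rose in 16 of 27 cases and fell in 4 (adjusted p = 0.224), or in 10 and 9 under the percentile of the detected probes and 19 and 3 under median scaling. As a list they passed upward with every probe as a feature (adjusted p = 0.00772). Hexokinase 2, Hk2, rose 2.61-fold and the glucose transporter Slc2a1 2.20-fold. The peptide hormone Adm (5.85-fold), Pfkfb3 (2.26-fold), Eno2 (-0.70) and Pfkfb4 (-0.25) fell. DNA and histone methylation enzymes rose in 10 of 29 cases, or 9 adjusted over the list alone, and fell in 5 (adjusted p = 0.71), and under the percentile of the detected probes 8 rose and 11 fell, with 9 each way under quantile normalization and 14 and 2 under median scaling. Uhrf1, which guides maintenance methylation to replicating DNA, rose 2.25-fold and the cytidine deaminase Apobec1 2.14-fold. The members that fell were the dioxygenase Tet1 (2.34-fold), the Polycomb methyltransferase Ezh1 (2.16-fold), Mbd4 (-0.45), Dnmt3a (-0.40) and Tet2 (-0.30).

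Adhesion molecules rose in 14 of 28 cases and fell in 9 (adjusted p = 0.485). With Itgb7, the protocadherin Pcdh7 rose 5.26-fold, and with Itga11 the mesenchymal cadherin Cdh11 fell 12.6-fold. Itgb1 (0.16), Pvrl3 (0.11), Sdc4 (-0.11), Itgav (0.092) and Itga1 (0.059) did not pass. Wnt and Notch genes had 6 of 14 members higher and 5 lower, or 4 and 6 under the percentile of the detected probes (adjusted p = 0.908 and 0.861). Their median of 0.13 and mean of 0.053 stood against a test that pointed down with camera and up with fry. The ligand Wnt5a rose 3.94-fold, and Notch3 was at least 2.01-fold higher. Notch3 lost its call without deletion-mutant replicate 1 or 2, where its fitted log2 change was 2.445 and 2.316. The Wnt antagonist Sfrp2 fell 15.8-fold, the receptors Fzd1 2.27-fold and Fzd2 by 0.84 (log2), Nkd2 by 0.59 and Wisp1 by 0.24. Hey1 (0.21), Sfrp1 (-0.18) and Dkk3 (0.046) did not pass.

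Markers of other cell types did not shift as lists. Of 6 measured adipocyte markers, 4 fell and 1 rose, Acsl1 at 0.82 (adjusted p = 0.104), and the list passed downward under median scaling (0.0319) and without deletion-mutant replicate 1 (0.0303). The lipoprotein lipase Lpl fell 3.53-fold, Dgat2, which makes triglycerides, 2.04-fold and Plin4 4.36-fold with 1 deletion-mutant array above background. The fatty acid binding protein Fabp4 was at least 2.62-fold lower, and Pparg (-0.074) did not pass. Fabp4 lost its call without wild-type replicate 1 or 2, where its fitted log2 change was -2.65 and -2.84. Of 5 bone and cartilage markers, 3 rose and 2 fell (adjusted p = 0.914), with a median of 0.47 against a mean of -0.43 and a test that pointed down. The phosphoprotein Spp1 rose 2.22-fold, Sox9 by 0.47 (log2) and the osteoblast factor Runx2 1.63-fold, while the matrix protein Mgp fell 3.54-fold and Comp was at least 1.53-fold lower. Runx2 lost its call without wild-type replicate 1, where its log2 change was 0.635. Of 7 leukocyte markers, 1 rose and 3 fell (adjusted p = 0.318), with a median of -0.10 and a mean of 0.051 where the test pointed down. The endotoxin receptor Cd14 rose 5.59-fold, the integrin Itgam fell 1.89-fold with its brightest probe but did not pass as a mean of its probes (adjusted p = 0.248), and Csf1r (0.17), Cd3e (-0.10) and Cd68 (-0.10) did not pass. Fcer1g (1.70-fold) and Aif1 (1.33-fold) fell, and both calls were lost without wild-type replicate 2, where their log2 changes were -0.734 and -0.372.

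The remaining marker lists had 4 measured members each and were not tested as lists. Of the skeletal muscle markers, Chrna1, Tnnt2 and Tnni1 (5.58-fold), a troponin of slow muscle, were higher and the skeletal actin Acta1 fell 12.8-fold. Of the epithelial markers, the keratin Krt8 was at least 2.79-fold higher, a call lost with no background filter (adjusted p = 0.0531). The claudin Cldn7 rose 1.43-fold, a call lost without deletion-mutant replicate 1, where its log2 change was 0.51. The keratin Krt14 fell 1.33-fold, a call lost under a variance model with an intensity trend (adjusted p = 0.0821), and Esrp1 (-0.26) did not pass. Of the endothelial markers, the TGF-beta co-receptor Eng was at least 2.32-fold lower. Pecam1 fell 1.32-fold and Egfl7 rose 1.19-fold, and neither call held without wild-type replicate 1 or 2. The log2 changes of Pecam1 were then -0.421 and -0.371, and those of Egfl7 0.226 and 0.286. The receptor Kdr (-0.028) did not pass.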

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

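All settings were planned except scaling on E1A spike-ins and on the percentile of detected probes, which were chosen after seeing the data, and the cause was not tested except where given. The 10631 changed features became 6466 of 34816 with no background filter. Without that filter 11107 features had an unadjusted p under 0.05 by limma, against 11604 with it. The 2423 features changed at least 2-fold became 1285 with normexp (693 higher and 592 lower), whose added offset compresses the folds of dim probes by construction, and 2472 to 2652 with 1 array left out. The Egfr signal of the deletion-mutant arrays lay at background, so its fitted change, -4.10 to -3.99 (log2) with 1 array left out, is no measured fold and shows no stability, and it gives no value under the filter on all 4 arrays. Of 25 lists, 10 passed with the preset correlation, 0 with an estimated correlation and 23 with fry, 9 to 11 with 1 array left out, 8 under the filter on all 4 arrays and under the detected-probe percentile, 12 under median scaling and 13 with every probe by itself. With the replicate number as a block, 9990 features, 2401 of them by at least 2-fold, and 9 lists passed, and the heat shock and NRF2 list had an adjusted p of 0.0571. Same-numbered arrays shared a row of the slide. Their deviations had a correlation of 0.047 across features, so little of the spread was shared by number. A slide block was not run, since there was 1 slide and 1 scan. Across 25 lists and 18 settings, 386 results stayed the same, 21 were weaker, 23 stronger and 18 turned direction, while adipocyte and bone markers had too few members for a value under the filter on all 4 arrays. Each of the 18 was a list that did not pass in either case. What turned was the direction that the test gives from its t-statistics; the values printed are mean shifts (log2) relative to other features unless given as p, and their sign stayed that of the shift under the 75th percentile. Methylation enzymes turned with every probe by itself (0.031), and ER chaperones under quantile normalization (0.04). Wnt and Notch genes turned with fry (adjusted p = 0.783), the detected-probe percentile (0.041), quantile normalization (0.036), without deletion-mutant replicate 2 (0.205) and without wild-type replicate 1 (0.162), with 0 to 0.205 over all 4 arrays left out in turn. Bone and cartilage markers turned with every probe (-0.262), the mean of probes (-0.454), normexp (-0.1) and the detected-probe percentile (-0.447). Chemokines turned with the filter on all 4 arrays (0.288), fry (adjusted p = 0.207), the detected-probe percentile (0.091), quantile normalization (0.077), the replicate block (0.091), and without wild-type replicate 1 (0.12) or 2 (0.142), with -0.039 to 0.142 over all 4. Across 134 named genes and 16 settings, 2076 results stayed the same, 42 lost their call and 0 turned direction, and the others had no value under the filter on all 4 arrays. Signal over background limits what these settings can show, since fewer than 50% of probes were well above background on each array.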

Other observations

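Gene families formed by name stem were chosen after their values were seen, and of 203 with at least 8 members, 22 passed with the preset correlation, 16 higher and 6 lower, but 0 with an estimated correlation (adjusted p = 0.864). The test with an estimated correlation rests on 2 residual degrees of freedom, so its failure says little here. The protocadherin beta genes, neuronal adhesion molecules encoded in a cluster on chromosome 18, were lower in 15 of 17 cases (median -1.02, adjusted p = 5.39e-05), such as Pcdhb14 (-1.29) and Pcdhb21 (-0.89), and 14 to 15 were lower under the other scalings. The Ly49 receptor genes of natural killer cells, Klra, were higher in 11 of 12 cases (median 3.29, adjusted p = 0.000637), such as Klra4 (3.55) and Klra22 (3.29), with Klra1 lower (-0.70). Their probes may share sequence and so report 1 transcript. The Serpina protease inhibitors on chromosome 12 were lower in 9 of 12 cases (median -2.02, adjusted p = 0.00956), among them Serpina3f, at least 6.45-fold. Under the other scalings 7 to 9 were lower, and 1 was higher under median scaling and under quantile normalization. Whether Serpina probes share sequence was not analysed.

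Among the families of the cell's basic machinery some were higher and others did not pass. All 14 measured Psmd genes, which encode a part of the 26S proteasome, were higher (median 0.58, adjusted p = 0.00247), and 11 to 14 were so under the other scalings. Nucleoporins of the Nup stem were higher in 16 of 17 cases (median 0.82, adjusted p = 0.000467). Mitochondrial ribosomal proteins were higher in 31 of 47 Mrpl genes (median 0.41, adjusted p = 0.000467) and 20 of 29 Mrps genes (median 0.34, adjusted p = 0.00247), but under the other scalings these counts ranged from 20 to 43 and from 13 to 27. Histone genes were higher in 29 of 39 cases and lower in 7 (median 0.86, adjusted p = 0.00426). Cytosolic ribosomal proteins did not pass, with 2 of 48 Rpl genes higher (median -0.013, adjusted p = 0.727) and 5 of 45 Rps genes (median -0.034, adjusted p = 0.779). The Ndufa (adjusted p = 0.531) and Cox stems (0.847) did not pass either. Nor did the Psmb stem (adjusted p = 0.385), although 7 of its 9 genes were higher and 1 lower, with a median of 0.44. Its failure to pass therefore does not set it apart from the Psmd genes.

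More than 50% of the tested features changed, and for this pattern the spike-in test and the common shift were chosen after the result was seen, while the other tests were written before theirs. A brightness difference common to all features is argued against, since no such shift brought the share past the threshold below 58.3%. Of the features changed at least 2-fold, 93.2% stayed so under E1A spike-in scaling, a weak test as it shifted all features by only 0.081 in log2. Neither test reaches a brightness difference that varies with signal or slide position. Probe GC content is argued against as well, since 58.7% of the tested features passed after each array's GC trend was removed, besides 97.2% of those changed at least 2-fold that stayed so. Whether a group is another mouse line than NIH3T3, which has lost the Cdkn2a locus, stays undecided: 0 of 4 probes of Cdkn2a and Cdkn2b were well above background on both arrays of 1 group only, which a line without that locus would also give. Open explanations are signalling by the mutant receptor, divergence of the cell populations during selection, a slide column effect, and a shared RNA extract within each group, which may make small differences pass.

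Mouse Egfr signal fell to background in deletion-mutant cells, and the test was chosen before its result was seen. Loss of a segment that holds most features within 2 Mb of Egfr is argued against. The other features there had a median log2 fold change of 0.119, and 11 of 12 were well above background on both deletion-mutant arrays. The nearest of them, Sec61g at 16401737 and 2810442I21Rik at 16835625, changed by -0.203 and -0.026. A loss confined to the stretch between these 2 features would not show in this test and stays undecided. Open explanations besides such a small loss are lower transcription of the cell's own Egfr gene and a mouse wild-type construct that the probes detect. Another is a deletion in the construct, which would have to remove the targets of both probes that passed the background filter. The values given here do not separate these explanations, as the labels give neither the species nor the extent of the deletion. Testing the hypothesis that active mutant receptor lowers the cell's own Egfr transcript would need probes that detect this transcript and not the construct.

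Neighbouring genes moved together: without name relatives, 62.8% of 239 adjacent pairs changed at least 2-fold had the same direction, above the highest of 1000 shufflings (60.7%), and the test of windows without name relatives was chosen only after the other results were seen. That share argues against paralogs whose probes share sequence as the only source. Windows of 50 features leave copy number of large segments undecided, with 8 of 1081 beyond 0.4 in log2, all above, against 5 at the 95th percentile and 10 at the highest of the shufflings, and those on chromosomes 13 and 6 span the histone and Klra clusters. Of pairs 20 places apart, 51.7% of 205 had the same direction (95th percentile of shufflings 56.1%). These pairs hold only features changed at least 2-fold. They argue against large segments that move genes that far and cannot show smaller shifts. Without name relatives 6 of 979 windows lay beyond 0.4, which equals the 95th percentile of shufflings and so leaves smaller shifts undecided. Open explanations are shared regulation of neighbouring genes, copy number changes of small segments, and those of large segments that move genes less than 2-fold. Copy number may differ between cell populations grown apart.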
